A study of Mus musculus with 9 samples.

How the data were processed

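RNA was measured in 9 mouse duodenum samples, 3 per group, with the groups taken from the treatment given in the sample labels. Per the labels' protocols, ribosomal RNA was removed and directional libraries were made. The values used are FPKM per gene as deposited, in 1 table of 54532 genes and 9 sample columns, with gene lengths and mm10 coordinates. The submitters' processing notes name fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build mm10, with no role or order. The annotation release, the strand setting of the counting and the exact formula of the FPKM are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart with certainty. Of the gene identifiers, 54409 were found in the mouse annotation GENCODE M21, and 98.33% of those have the same start and end there.

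Each deposited FPKM multiplied by the gene length was a whole multiple of 1 step per library, within a tolerance of 0.1 reads, for 99.98% to 100% of the values above 0. The recovered reads assigned to genes ranged from 15373260 in CeD 1 to 16852104 in control 3. The steps correspond to effective library sizes of 14410551 to 18206427, which are not these totals but 1 constant of 16050000 times median-of-ratios factors of 0.898 to 1.13, so the deposited FPKM were already scaled between libraries. Transcripts of the mitochondrial genome took 4.15% to 10.2% of the reads. The median standard error of a log2 fold change between 2 groups was 0.348.

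Since FPKM are not counts, no count test was used for the values given, and limma-voom on recovered reads was added only as an alternative. Values were taken as log2(FPKM + 0.5) without further scaling, and genes with a mean of at least 0.5 FPKM over the 9 libraries were kept, 14683 genes of which 12391 are protein-coding. Groups were compared with limma 3.58.1 in R 4.3.3, in 1 group-means model over all 9 libraries with empirical Bayes moderation and a mean-variance trend, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. All tests were two-sided. With 3 libraries against 3 an exact permutation test cannot give a p under 0.1, so the adjusted p-values come from limma or from camera.

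Of 46 gene lists of pathways and cell types, 44 had at least 3 tested members. They were tested with camera of limma at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with a correlation estimated per list and with fry, which asks whether the genes of a list move on balance in 1 direction. With the preset correlation 13, 9 and 18 lists were called in CeD against control, CeD+GR against CeD and CeD+GR against control. With an estimated correlation 0 were called in each, with smallest adjusted p of 0.74, 0.87 and 0.84, and fry called 0. Among the lists that were not called, the median and the test differed in sign for 4, 7 and 3 lists. The overlap of the first 2 comparisons was set beside 100 simulated regroupings of unchanged groups, in which the 2 comparisons share 1 simulated group. After the data were seen, 100 regroupings with 1 replicate 1 library in each group were added, each fitted again with limma.

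Named genes follow a rule. For each of the first 2 comparisons it takes up to 8 protein-coding genes per direction that passed with no overlap between the groups, filled up to 5 by the smallest unadjusted p where fewer passed, with a mean of at least 1 FPKM in the higher group. It adds up to 3 members of each list with the smallest unadjusted p, and 16 genes that could always be named, such as Ifng, Il15, Tgm2 and Foxp3. Immunoglobulin and T cell receptor segments were left out of the first part, as were predicted genes. For CeD+GR against control it takes 3 genes per direction. Other genes are said to be chosen after their values were seen. Some genes that the rule takes are not reported here. The groups, tests, lists, naming rule and the first set of alternatives named below were fixed before the data were examined.

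The steps were tested on simulated values with the spread of these libraries. For CeD against control, over 14683 genes, limma recovered 12%, 62%, 82% and 86% of genes changed by a log2 fold of 1, 2, 3 and 4, and called 8 unchanged genes. The simulated noise was independent between libraries, without the difference of replicate 1 described below, so these shares need not hold for the real libraries. Of 20 lists shifted by 0.5, 20 were called with camera, and 0 of 40 lists that were not shifted, in simulated genes that vary independently of each other.

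The first set of alternatives used pseudocounts of 0.1 and 1, no filter or a mean of at least 2 FPKM, rescaling by median-of-ratios factors, quantile normalization, a fit of only the groups compared, no mean-variance trend, array weights, the replicate number as a block, protein-coding genes only, and each library left out in turn. After the data were seen, 5 more were added, namely limma-voom on the recovered reads, a term for replicate 1 against replicates 2 and 3, replicates 2 and 3 only, CeD 1 and CeD+GR 3 left out, and both left out together with that term.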

Results

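Duodenal tissue of mice was profiled by directional RNA sequencing after removal of ribosomal RNA, in 3 groups of 3 libraries. Control mice were wild type and received gluten without the enhanced stimulation. CeD mice were a delayed-type hypersensitivity model of celiac disease, the immune enteropathy driven by dietary gluten, and received enhanced gluten stimulation. CeD+GR mice were the same model and were first given composite nanoparticles that carried gliadin, a fraction of gluten proteins, together with rapamycin, an inhibitor of the mTOR kinase. Libraries are named by group and replicate number. Between 15373260 and 16852104 reads per library were assigned to genes, and 14683 genes with a mean of at least 0.5 FPKM were tested. Fold changes are on the scale of log2(FPKM + 0.5), which understates the change of genes with low values. The sample labels do not say whether the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

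Several libraries held transcripts of neighbouring tissues or cell types, in genes chosen after their values were seen. In CeD+GR 3, Tff2, a secreted peptide of gastric mucous cells, reached 116200 FPKM and took 6.87% of the reads, against at most 46.5 FPKM elsewhere. Muc6, a mucin of gastric and duodenal glands, stood at 3268 FPKM in that library and at 0.0839 FPKM or less in the others. In CeD 1, Ctrb1, which encodes the pancreatic enzyme precursor chymotrypsinogen B, stood at 1472 FPKM and at 22.5 FPKM or less elsewhere. In CeD+GR 2, the fat cell hormone Adipoq reached 26.6 FPKM, against 1.51 FPKM or less in the other libraries. All 3 libraries with replicate number 1 were high in Paneth cell transcripts. Defa24, an alpha-defensin whose reads may be shared with near-identical family members, stood at 611, 1092 and 1332 FPKM in control 1, CeD 1 and CeD+GR 1, and between 27.9 and 77.8 FPKM in the other 6 libraries. Pdx1, a transcription factor of the proximal duodenum and pancreas, stood at 26.0 to 27.2 FPKM in control. It stood at 25.3, 12 and 6.64 FPKM in CeD 1 to 3, and at 1.59, 0.118 and 46.0 FPKM in CeD+GR 1 to 3. Across the tested genes, the replicate 1 libraries correlated with each other at 0.950 to 0.974, and with replicates 2 and 3 of control and CeD at 0.881 to 0.941. CeD+GR 3 correlated with the other libraries at 0.785 to 0.855; genes are not independent replicates.

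**Figure D1:**
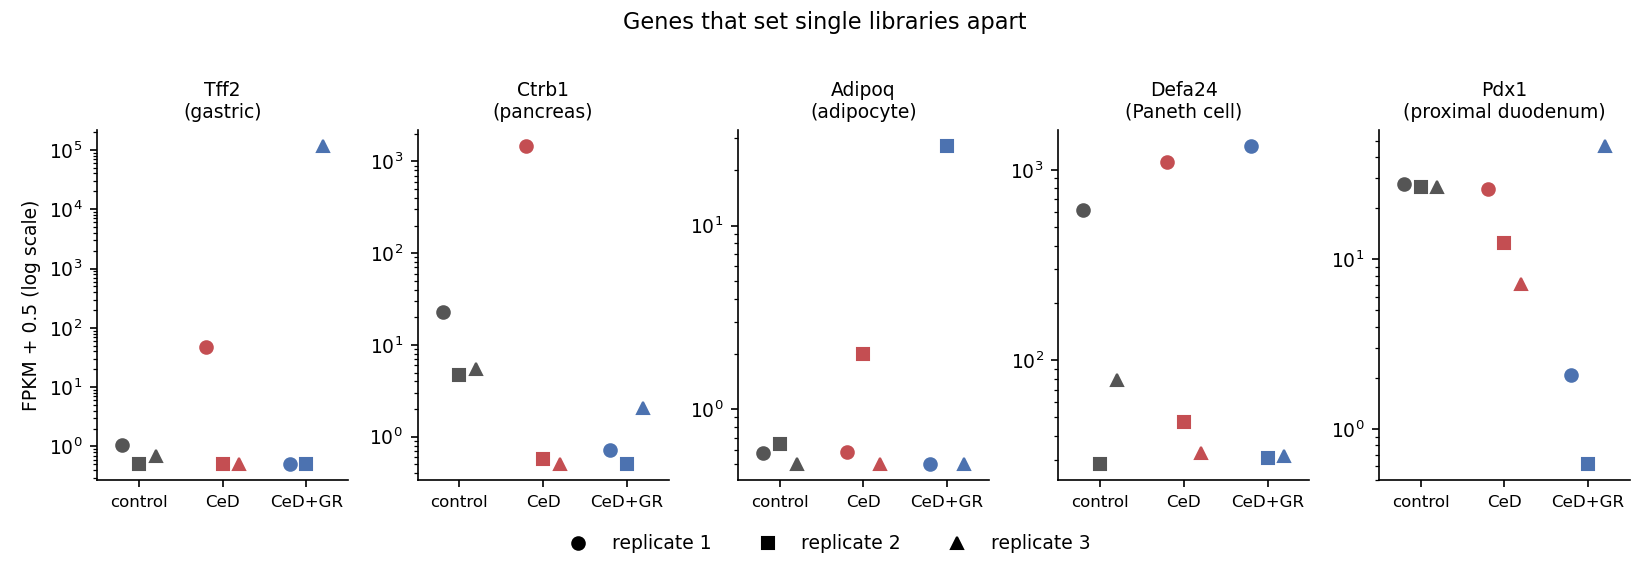
Expression of 5 genes per library, as FPKM + 0.5 on a log axis, with each group on the horizontal axis and 1 symbol shape per replicate number. Tff2 stands at 116200 FPKM in CeD+GR 3 alone, Ctrb1 at 1472 FPKM in CeD 1 and Adipoq at 26.6 FPKM in CeD+GR 2, while Defa24 lies between 611 and 1332 FPKM in the 3 replicate 1 libraries and Pdx1 ranges from 0.118 to 46.0 FPKM.

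The comparison of CeD with control asked how the duodenum of the hypersensitivity model under enhanced gluten stimulation differs from that of wild-type mice without it. Markers of cytotoxic and intraepithelial lymphocytes were lower in CeD. Of 15 tested members, 14 had a negative log2 fold change, with a median of -0.67 (camera of limma, adjusted p = 8e-17; adjusted p = 0.74 with an estimated correlation). Cd8a, which encodes the alpha chain of the CD8 co-receptor (ENSMUSG00000053977, mm10 chromosome 6, 71373427 to 71379173), averaged 13.2 ± 2.27 FPKM (SD, n = 3) in control and 6.46 ± 0.774 FPKM in CeD, a log2 fold change of -0.97 (SE 0.31). Gzmb, the cytotoxic granule protease granzyme B (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), averaged 48.5 ± 6.63 and 25.2 ± 1.27 FPKM. Klrd1, the CD94 receptor of natural killer and T cells (ENSMUSG00000030165, chromosome 6, 129591782 to 129598775), averaged 10 ± 2.6 and 2.72 ± 0.222 FPKM, and Fasl, the death receptor ligand, 2.92 ± 0.716 and 1.26 ± 0.0503 FPKM. Every control library lay above every CeD library for these 4 genes, but none of the 15 members passed singly in limma, over all genes or adjusted over the list alone (0 each). The mean log2 level of the list ran from 2.91 to 3.24 in control and from 2.23 to 2.59 in CeD; the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. With replicates 2 and 3 only, the median was -0.65, and replicate 1, with 1 library per group, allows no test of its own.

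T cell markers were lower as well, with 15 of 16 members negative and a median of -0.57 (adjusted p = 1.2e-08; adjusted p = 0.74 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, averaged 7.41 ± 1.57 FPKM (SD, n = 3) in control and 3.51 ± 0.766 FPKM in CeD, and Cd3e averaged 2.29 ± 0.527 and 1.28 ± 0.197 FPKM. Leaving out control 2 moved the median of the list to -0.38. Regulatory T cell and tolerance genes had a median of -0.29 with 8 of 12 members negative (adjusted p = 0.012; adjusted p = 0.74 with an estimated correlation), and Ctla4, an inhibitory T cell receptor, averaged 4.81 ± 4.33 and 1.41 ± 1.07 FPKM. That call ended without control 1, control 3 or CeD 2, at medians of -0.15, -0.18 and -0.14. It also ended at 0.07 among genes of at least 2 FPKM, at -0.24 with array weights, at -0.22 with replicates 2 and 3 only, and at -0.30 with CeD 1 and CeD+GR 3 left out and a term for replicate 1. Plasma cell markers had a median of -0.44, with 11 of 13 negative (adjusted p = 0.0044; adjusted p = 0.74 with an estimated correlation), and Mzb1, a chaperone of antibody secretion, averaged 17.1 ± 3.98 and 12.3 ± 3.02 FPKM. The plasma cell call ended at -0.27 without control 1, -0.16 without CeD 2 and -0.19 without CeD 3, and the median was -0.24 without control 3. No member of these 3 lists passed in limma, over all genes or adjusted over the list alone (0 each).

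**Figure D2:**
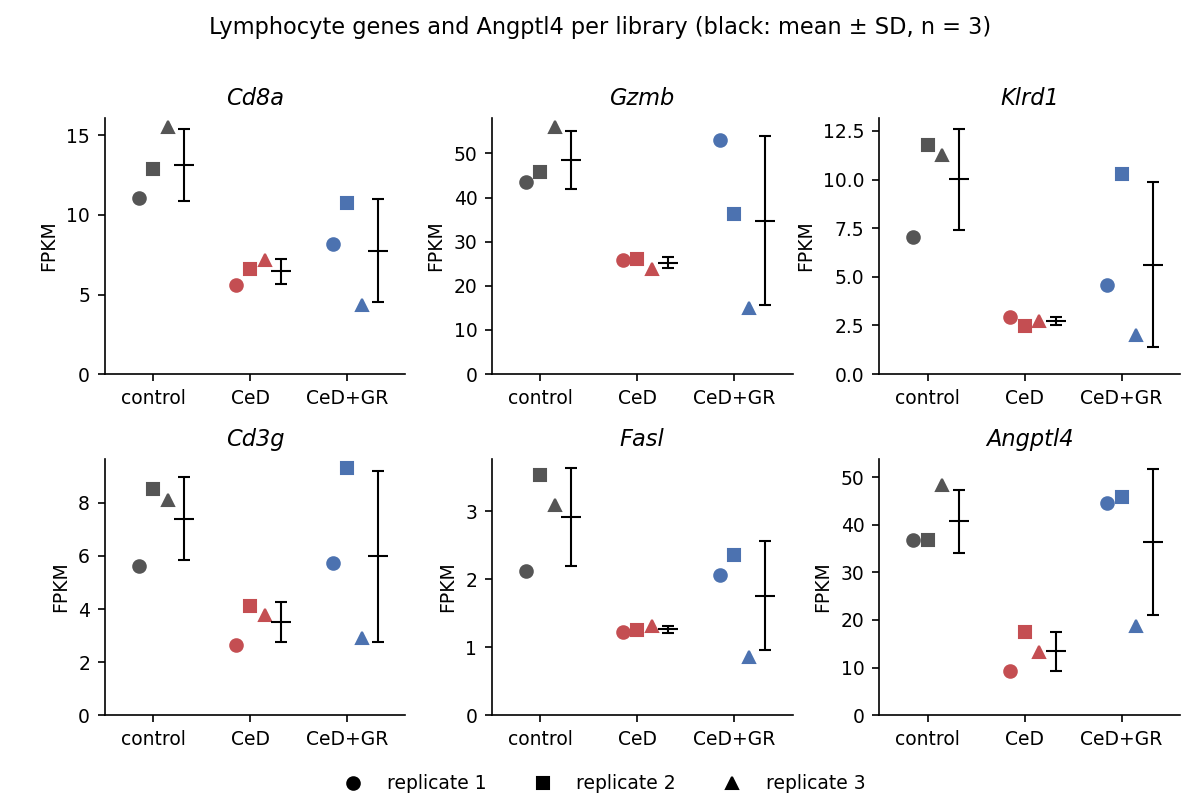
FPKM per library (vertical axis, linear, from 0) of 6 genes in the 3 groups, with 1 symbol shape per replicate number and the mean ± SD (n = 3) in black. Cd8a averaged 13.2 FPKM in control and 6.46 FPKM in CeD and Angptl4 40.7 and 13.4 FPKM, with no overlap of the libraries, while CeD+GR spread from 4.34 to 10.8 FPKM for Cd8a.

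Type I interferon, MHC class I and interferon gamma lists were lower in CeD than in control in the list tests. Their list means gave a two-sided exact permutation p of 0.3 each. The MHC class II presentation list, which shares Ciita with the interferon gamma list, was not lower. It had a median of 0.08 with 8 of 10 members positive (camera adjusted p = 0.5). The type I interferon list had a median of -0.38 with 24 of 26 members negative (camera adjusted p = 3.8e-06; adjusted p = 0.74 with an estimated correlation). Mx1 and Ifit2, both antiviral effectors, averaged 4.09 ± 2.06 and 7.76 ± 4.19 FPKM (SD, n = 3) in control and 2.40 ± 0.669 and 4.11 ± 1.02 FPKM in CeD. This call ended at a median of -0.28 without control 1 and -0.14 without CeD 1, the library with pancreatic transcripts, and the median was -0.24 without control 2. The MHC class I presentation list had a median of -0.23 with 15 of 16 negative (adjusted p = 0.0014; adjusted p = 0.74 with an estimated correlation). Tap1, the peptide transporter, averaged 51.1 ± 8.82 and 36.9 ± 10.6 FPKM, and H2-Q6, whose reads may be shared with other H2-Q genes, 48.5 ± 7.43 and 28.4 ± 7.62 FPKM. That call ended at -0.01 without CeD 1, and the median was -0.43, -0.11, -0.38 and -0.48 without control 1, control 2, CeD 2 and CeD 3. The interferon gamma list had a median of -0.19 with 20 of 25 negative (adjusted p = 0.002; adjusted p = 0.74 with an estimated correlation). Cxcl10, a chemokine for activated T cells, averaged 6.81 ± 1.50 and 4.29 ± 3.19 FPKM. The interferon gamma call ended without control 1 and without CeD 1, the latter at -0.22, and the median was -0.35 without control 3 and -0.30 without CeD 3. With replicates 2 and 3 only, the medians were -0.08 for the type I list, -0.24 for MHC class I and -0.13 for interferon gamma, none of them called. The type I call also ended with array weights, at -0.28, and with CeD 1 and CeD+GR 3 left out and a term for replicate 1 the type I and interferon gamma calls ended at -0.31 and -0.14. No member of the 3 lists passed in limma, over all genes or adjusted over the list alone (0 each).

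Lists of stromal, blood and other tissues were higher in CeD than in control. Fibroblast and extracellular matrix genes had a median of 0.42 with 17 of 19 positive (camera adjusted p = 1.2e-05; adjusted p = 0.74 with an estimated correlation). The matrix proteoglycans Lum and Dcn averaged 2.22 ± 0.520 and 8.58 ± 5.99 FPKM (SD, n = 3) in control and 4.07 ± 0.662 and 15.9 ± 5.98 FPKM in CeD. Leaving out CeD 1 ended this call at 0.09, and the median was 0.77, 0.19 and 0.21 without control 1, 2 and 3 and 0.74 and 0.28 without CeD 2 and 3. Smooth muscle markers had a median of 0.40 with 12 of 14 positive (adjusted p = 0.0031; adjusted p = 0.74 with an estimated correlation), which was 0.15 and not called without control 1, -0.05 without CeD 3 and 0.84 without CeD 1. Erythroid markers had a median of 0.66 with 5 of 5 positive (adjusted p = 0.0048; adjusted p = 0.74 with an estimated correlation). It was 0.29 and not called without CeD 2, and 1.07, 0.33 and 1.13 without CeD 3, control 3 and control 1. Pancreas markers had a median of 0.93 with 20 of 22 positive (camera adjusted p = 0.00032, and 0.74 with an estimated correlation). The median was 1.82 and 1.90 without CeD 2 and CeD 3. Without CeD 1 it turned to -1.23, and the list was called lower (camera adjusted p = 1e-27 at the preset correlation). The list mean was 6.58, 0.02 and -0.18 in CeD 1 to 3 and 0.98 to 1.78 in control. The pancreas call also ended at 0.45 with a pseudocount of 0.1 and -0.09 with limma-voom. Proliferation genes had a median of 0.30 with 22 of 23 positive (adjusted p = 0.04; adjusted p = 0.97 with an estimated correlation). It turned to -0.29 without CeD 1, was 0.06 and 0.07 and not called without control 2 and 3, lost its call without CeD+GR 3, and was 0.98, 0.59 and 0.75 without control 1, CeD 2 and CeD 3. The proliferation call also ended with a pseudocount of 0.1, no filter, median-of-ratios rescaling, a fit of only these groups and replicates 2 and 3 only, at 0.25 to 0.38. Cytosolic ribosomal protein genes had a median of -0.17 with 33 of 35 negative (adjusted p = 0.00012; adjusted p = 0.74 with an estimated correlation), and Rps23 averaged 188 ± 22.3 and 144 ± 17.4 FPKM. The ribosomal call ended at -0.07 without control 1, and the median was -0.11 without CeD 2, -0.09 without CeD 3 and -0.33 without CeD 1. With CeD 1 and CeD+GR 3 left out and a term for replicate 1, the erythroid and ribosomal calls ended at 0.72 and -0.10. None of the members of these lists passed in limma, over all genes or adjusted over the list alone (0 each).

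Of genes linked to celiac disease, Il15, an epithelial cytokine that activates intraepithelial lymphocytes, averaged 12.2 ± 3.45 FPKM (SD, n = 3) in control and 13.7 ± 4.58 FPKM in CeD. Tgm2, the transglutaminase that deamidates gliadin, averaged 13.6 ± 7.62 and 15.2 ± 6.33 FPKM. Both differences were smaller than the spread between libraries. Il21r, the receptor of interleukin 21, averaged 1.98 ± 0.387 and 0.879 ± 0.299 FPKM, a log2 fold change of -0.86 (SE 0.32). The cytokines Ifng, Il21, Il17a and Il10 had 11, 2, 1 and 45 reads in all 9 libraries together, and a difference between groups was not detectable at this depth. Enterocyte absorption and digestion genes had a median of 0.10 (camera adjusted p = 0.53) and tight junction genes a median of 0.00 (adjusted p = 0.53). The enterocyte list was called higher in CeD without control 2, at 0.25, and without CeD 1, at 0.46 (adjusted p = 0.97 over all libraries with an estimated correlation).

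Single genes with the smallest unadjusted p and no overlap between CeD and control are given as values, since none passed. Angptl4, a secreted inhibitor of lipoprotein lipase (ENSMUSG00000002289, chromosome 17, 33773750 to 33781575), averaged 40.7 ± 6.64 FPKM (SD, n = 3) in control and 13.4 ± 4.09 FPKM in CeD, a ratio of 0.330. Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), averaged 0.693 ± 0.360 and 17.7 ± 20.4 FPKM, with 10.8, 40.7 and 1.61 FPKM in CeD 1 to 3. Lnx1, Mpc1 and Flcn had log2 fold changes of 0.69 (SE 0.23), 0.72 (SE 0.27) and 0.67 (SE 0.26). Mpc1 encodes part of the mitochondrial pyruvate carrier, and Flcn encodes folliculin, a regulator of mTORC1. Dnajb3, Parp3 and Als2cl had log2 fold changes of -1.16 (SE 0.36), -0.68 (SE 0.22) and -0.74 (SE 0.24). Over all 14683 genes, limma called 0 genes higher and 0 lower at an adjusted p of 0.05, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 40 higher and 63 lower genes. Freely exchangeable libraries would give 734 in all, but each group holds 1 replicate 1 library, and these stand apart. Simulated unchanged groups that keep this balance gave 251 on average (SD 316, range 0 to 1471, 100 regroupings), too wide a spread to judge the number. Limma-voom on recovered reads also called 0, with 27 higher and 37 lower at an unadjusted p under 0.05. The total of 103 was far from stable on the same genes. It rose to 1354 with array weights (smallest adjusted p of 0.07), to 787 with CeD 1 and CeD+GR 3 left out and a term for replicate 1, to 414 without control 1, to 304 with replicates 2 and 3 only and to 200 with that term alone, and fell to 53 without control 3. In 4.69% of genes the 2 groups did not overlap, where freely exchangeable libraries would give 10%. With a replicate 1 library apart in each group, that share need not hold here.

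The comparison of CeD+GR with CeD asked what the nanoparticles change in the challenged model. Cytosolic ribosomal protein genes were higher in CeD+GR, with 35 of 35 members positive and a median log2 fold change of 0.51 (camera of limma, adjusted p = 9.1e-13; adjusted p = 0.87 with an estimated correlation). The mean log2 level of the list was 7.44, 6.42 and 7.59 in CeD+GR 1 to 3 and 6.49 to 6.93 in CeD. CeD+GR 2 thus lay below every CeD library (two-sided exact permutation p = 0.4). Rps20 (ENSMUSG00000028234, mm10 chromosome 4, 3831334 to 3835665) averaged 54.1 ± 1.22 FPKM (SD, n = 3) in CeD and 84.8 ± 18.7 FPKM in CeD+GR, and Rps23 (ENSMUSG00000049517, chromosome 13, 90922958 to 90924950) 144 ± 17.4 and 233 ± 51.0 FPKM. Endothelial markers were higher too, with 11 of 11 positive and a median of 0.60 (camera adjusted p = 0.00019, and 0.87 with an estimated correlation). The list mean was 2.26, 2.14 and 2.4 in CeD+GR 1 to 3 and 2.29, 1.21 and 1.32 in CeD 1 to 3. CeD 1 thus lay within the range of CeD+GR (two-sided exact permutation p = 0.3). Esam, an adhesion molecule of endothelial junctions (ENSMUSG00000001946, chromosome 9, 37528078 to 37538319), averaged 2.41 ± 0.740 and 6.93 ± 2.39 FPKM, and Cldn5 1.75 ± 0.279 and 4.72 ± 4.42 FPKM. The ribosomal median was 0.85 without CeD+GR 2 and 0.28 without CeD+GR 3, the endothelial median 0.99 without CeD 1 and 0.34 without CeD 2, and all 4 stayed called. With CeD 1 and CeD+GR 3 left out and a term for replicate 1, the ribosomal call ended at 0.18. With replicates 2 and 3 only, the medians were 0.46 and 0.97. No member of either list passed in limma, over all genes or adjusted over the list alone (0 each).

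Smooth muscle, enteric neuron, enterocyte and xenobiotic metabolism genes were lower in CeD+GR than in CeD. Smooth muscle markers had a median of -0.80 with 13 of 14 negative (camera adjusted p = 9.4e-06; adjusted p = 0.87 with an estimated correlation). The contractile proteins Myh11 and Synpo2 averaged 119 ± 78.2 and 11.5 ± 6.37 FPKM (SD, n = 3) in CeD and 37.9 ± 18.8 and 3.71 ± 1.52 FPKM in CeD+GR. This call ended at -0.17 without CeD+GR 1, and the median was -1.28 without CeD 1 and -0.31 without CeD 3. Enteric neuron and glia markers had a median of -0.69 with 10 of 12 negative (adjusted p = 0.00019; adjusted p = 0.87 with an estimated correlation), and the neuronal tubulin Tubb3 averaged 5.96 ± 3.73 and 2.12 ± 1.76 FPKM. That call ended at -0.42 without CeD 3 and -0.54 without CeD+GR 1, and the median was -1.25 without CeD+GR 2. Enterocyte absorption and digestion genes had a median of -0.55 with 26 of 27 negative (adjusted p = 0.00019; adjusted p = 0.95 with an estimated correlation), and Mgam, the brush border maltase-glucoamylase, averaged 529 ± 215 and 291 ± 141 FPKM. The enterocyte median turned to 0.29 without CeD+GR 3, the library with gastric transcripts, was -0.23 and not called without CeD 2, and was -0.85, -0.89 and -0.90 without CeD 1, CeD+GR 1 and CeD+GR 2. Xenobiotic and retinoid metabolism genes had a median of -0.62 with 18 of 20 negative (adjusted p = 4e-05; adjusted p = 0.87 with an estimated correlation). The detoxifying transferase Gstm1 averaged 284 ± 18.6 and 147 ± 68.4 FPKM. Without CeD+GR 3 the xenobiotic call ended at -0.04, and the median was -0.39 without CeD 2 and -1.07 without CeD+GR 1. With CeD 1 and CeD+GR 3 both left out, the enterocyte and xenobiotic calls ended at -0.10 and -0.18. No member of the 4 lists passed in limma, over all genes or adjusted over the list alone (0 each).

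Lists of neighbouring tissues followed single libraries. Gastric and Brunner gland markers had a median of 3.35 with 9 of 9 positive in CeD+GR against CeD (camera adjusted p = 0.00057; adjusted p = 0.87 with an estimated correlation), which turned to about 0 (-0.04) without CeD+GR 3 and was 5.04 without CeD+GR 1 or CeD+GR 2. Pancreas markers had a median of -2.21 with 22 of 22 negative (adjusted p = 3.6e-06; adjusted p = 0.87 with an estimated correlation), which turned to 0.29 without CeD 1 and was -3.46 and -3.60 without CeD 2 and CeD 3. The pancreas call also ended with array weights, at -0.72. The type I interferon list had a median of -0.27 with 22 of 26 negative (adjusted p = 0.011; adjusted p = 0.95 with an estimated correlation). That call ended without CeD 3, CeD+GR 1 or CeD+GR 3, at medians of -0.04, -0.04 and -0.02, and the median was -0.44 without CeD 1 and -0.65 without CeD+GR 2. It also ended at -0.29 with replicates 2 and 3 only and at -0.23 with CeD 1 and CeD+GR 3 left out. No member of these lists passed in limma, over all genes or adjusted over the list alone (0 each).

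The lymphocyte lists that were lower in CeD were not called between CeD+GR and CeD. T cell markers had a median of 0.16 with 14 of 16 positive (camera adjusted p = 0.086) and cytotoxic lymphocyte markers a median of 0.20 with 12 of 15 positive (adjusted p = 0.16). Gzmb stood at 53.1, 36.2 and 15.0 FPKM in CeD+GR 1 to 3, and Cd8a at 8.17, 10.8 and 4.34 FPKM. Klrd1 averaged 2.72 ± 0.222 FPKM (SD, n = 3) in CeD and 5.63 ± 4.25 FPKM in CeD+GR, Cd3g 3.51 ± 0.766 and 5.99 ± 3.22 FPKM, and the T cell receptor constant gene Trac 6.57 ± 0.458 and 11.1 ± 5.20 FPKM. Without CeD+GR 3, the library with gastric transcripts, T cell, cytotoxic and regulatory T cell lists were called higher in CeD+GR, at medians of 0.53, 0.56 and 0.49. Over all libraries their adjusted p with an estimated correlation was 0.95, 0.95 and 0.87. Markers of other tissues and cells also differed in that fit, with smooth muscle at -1.17, enteric neurons at -0.47, adipocytes at 1.46, pancreas at -2.34, endothelium at 0.57 and macrophages and dendritic cells at 0.36, all called (adjusted p = 0.87 to 0.95 over all libraries with an estimated correlation). T cell markers were also called without CeD 3, at 0.29, and cytotoxic markers without CeD 2, at 0.28. The regulatory T cell list, at 0.26 over all libraries (adjusted p = 0.06), was also called without CeD 1, at 0.32, and at 0.26 without control 2 or control 3. With replicates 2 and 3 only, the medians were 0.10 for T cells and 0.00 for cytotoxic lymphocytes, not called. Ctla4 averaged 1.41 ± 1.07 and 4.14 ± 2.20 FPKM, and Tgfb1, a cytokine of immune tolerance, 1.69 ± 0.511 and 3.60 ± 1.48 FPKM. Il18, an epithelial cytokine, averaged 120 ± 28.8 and 67.4 ± 31.7 FPKM.

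Genes of the mTOR pathway, the target of rapamycin, had a median log2 fold change of 0.02 between CeD+GR and CeD (camera adjusted p = 0.88), and mTORC1-linked glycolysis and one-carbon genes a median of 0.01 (adjusted p = 0.79). Mtor itself averaged 4.11 ± 1.85 FPKM (SD, n = 3) in CeD and 2.93 ± 1.69 FPKM in CeD+GR. These are levels of RNA, and the activity of the kinase that rapamycin inhibits was not measured. Autophagy and lysosome genes had a median of 0.13 with 18 of 23 positive (adjusted p = 0.086), and were called higher at 0.21 without CeD 2 (adjusted p = 0.95 over all libraries with an estimated correlation).

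Among single genes with no overlap between CeD+GR and CeD, none of which passed, Bok had the smallest unadjusted p. Bok, a member of the Bcl-2 family of apoptosis regulators (ENSMUSG00000026278, chromosome 1, 93685660 to 93695764), averaged 6.40 ± 1.21 FPKM (SD, n = 3) in CeD and 25.8 ± 7.82 FPKM in CeD+GR, 3.75-fold higher (SE 0.30 on the log2 scale). Mmp15, a membrane-bound matrix metalloproteinase (ENSMUSG00000031790, chromosome 8, 95352268 to 95375080), averaged 5.09 ± 1.22 and 10.7 ± 2.54 FPKM. Npc2, a lysosomal carrier of cholesterol, had a log2 fold change of 0.77 (SE 0.18), the peptide transporter Slc15a2 1.68 (SE 0.38) and the lymphocyte receptor P2ry10 1.60 (SE 0.41). On the lower side, the guidance molecule Ntn1 had a log2 fold change of -1.33 (SE 0.29), Adgra2 -1.56 (SE 0.33), Slc10a4 -1.84 (SE 0.43), Lpp -0.76 (SE 0.18) and Gucy1b1, a subunit of soluble guanylate cyclase, -0.89 (SE 0.21). Over all 14683 genes, limma called 0 genes, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 167 higher and 258 lower genes, where freely exchangeable libraries would give 734 in all. Simulated unchanged groups with 1 replicate 1 library each gave 396 on average (SD 460, range 0 to 1776, 100 regroupings). With limma-voom 0 genes were called, and 105 higher and 277 lower genes had an unadjusted p under 0.05. On the same genes the total of 425 rose above 734 without CeD+GR 1 (1116) or CeD+GR 2 (940) and with replicates 2 and 3 only (809). It also did so with a term for replicate 1 (789) and with CeD 1 and CeD+GR 3 left out as well as that term (1870). It fell to 226 without CeD 2. In 6.05% of genes the groups did not overlap, against 10% for freely exchangeable libraries, a share that need not hold with replicate 1 apart.

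The remaining comparison, CeD+GR with control, asked how far treated mice of the model stood from control mice. Type I interferon response genes were lower in CeD+GR, with 25 of 26 members negative and a median log2 fold change of -0.62 (camera of limma, adjusted p = 2e-09; adjusted p = 0.84 with an estimated correlation). Ifit1bl1 averaged 116 ± 42.1 FPKM (SD, n = 3) in control and 55.5 ± 11 FPKM in CeD+GR, and Mx1 4.09 ± 2.06 and 1.67 ± 0.280 FPKM, both chosen after their values were seen. The interferon median was -1.0 without CeD+GR 2 and -0.38 without CeD+GR 3, and with replicates 2 and 3 only it was -0.32 and not called. Cytotoxic and intraepithelial lymphocyte markers were lower, with 14 of 15 negative and a median of -0.57 (adjusted p = 1.2e-05; adjusted p = 0.84 with an estimated correlation), and the median was -0.26 without CeD+GR 3. This call ended when CeD 1 was left out together with CeD+GR 3, also at -0.26. Erythroid markers were higher, with 5 of 5 positive and a median of 1.37 (adjusted p = 0.00034; adjusted p = 0.84 with an estimated correlation). With CeD 1 and CeD+GR 3 left out and a term for replicate 1, the erythroid call ended at 1.64, and the median was 0.50 without a filter on low values. No member of the 3 lists passed in limma, over all genes or adjusted over the list alone (0 each).

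The 18 lists called between CeD+GR and control with camera include 15 further ones, all with an adjusted p of 0.84 or 0.85 with an estimated correlation and with no member passing over all genes or adjusted over the list alone (0 each). Higher medians were 3.39 for gastric markers, 1.04 for adipocytes, 0.64 for endothelium, 0.39 for fibroblasts, 0.32 for ribosomal proteins and 0.27 for enteroendocrine cells. Lower medians were -1.07 for pancreas, -0.56 for smooth muscle, -0.55 for enteric neurons, -0.49 for xenobiotic metabolism, -0.48 for enterocytes, -0.36 for MHC class I, -0.32 for interferon gamma, -0.23 for oxidative stress and -0.21 for T cells. Leaving out CeD+GR 3, with its gastric transcripts, brought the medians of the gastric, MHC class I and interferon gamma lists to 0.00 and that of xenobiotic metabolism to -0.05, and turned enterocytes to 0.41 (called higher) and T cells to 0.11. It also ended the calls of ribosomal proteins at 0.14, fibroblasts at 0.29, oxidative stress at -0.13, pancreas at -1.24 and enteric neurons at -0.26. Without CeD+GR 2, with its adipocyte transcripts, the adipocyte median turned to -0.42 and the calls of enteroendocrine cells, fibroblasts, oxidative stress and pancreas ended at 0.30, 0.39, -0.25 and -1.17. Without CeD+GR 1 the smooth muscle median turned to 0.02, the enteroendocrine median to -0.21, and the calls of T cells, enteric neurons, ribosomal proteins and pancreas ended at -0.27, -0.42, 0.18 and -1.06. Leaving out control 2 ended the calls of endothelium at 0.23, enterocytes at -0.30, MHC class I at -0.21, T cells at -0.26, enteric neurons at -0.44, enteroendocrine cells at 0.01, fibroblasts at 0.29, smooth muscle at -0.41 and oxidative stress at -0.19. Control 3 did so for enteric neurons, fibroblasts, smooth muscle and oxidative stress at -0.41, 0.21, -0.47 and -0.14, and control 1 for interferon gamma, adipocytes and pancreas at -0.31, 1.02 and -0.84. Other omissions moved called lists further from 0. Without CeD+GR 2 the medians were -0.77 for MHC class I, -0.60 for interferon gamma, -0.62 for T cells, -0.76 for enterocytes, -0.96 for enteric neurons and 0.62 for ribosomal proteins. Without CeD+GR 1 they were -0.48 for interferon gamma, -0.91 for enterocytes, -0.91 for xenobiotic metabolism and 1.65 for adipocytes, and without CeD+GR 3 they were 0.64 for enteroendocrine cells and 1.65 for adipocytes. Without control 1 they were 0.62 for enteroendocrine cells, 0.65 for fibroblasts, -0.54 for MHC class I and -0.36 for T cells. Taking replicates 2 and 3 only, the calls of interferon gamma, T cells, enteroendocrine cells, smooth muscle, enteric neurons and adipocytes ended at -0.45, -0.32, 0.15, -0.20, -0.55 and 1.63. Array weights ended those of interferon gamma, enterocytes, xenobiotic metabolism, oxidative stress, pancreas and adipocytes at -0.19, -0.21, -0.32, -0.21, -1.02 and 0.52. With CeD 1 and CeD+GR 3 left out and a term for replicate 1, endothelium also ended, at 0.41. Among genes of at least 2 FPKM, T cells, enteroendocrine cells, enteric neurons and adipocytes ended, the second of these at -0.01, and with limma-voom enteroendocrine cells and adipocytes ended at 0.29 and 0.32. Without a filter on low values the enteroendocrine and pancreas calls ended at 0.15 and -0.93. The pancreas call also ended with a pseudocount of 1, median-of-ratios rescaling and quantile normalization, and the adipocyte call with a pseudocount of 0.1 and with the term for replicate 1.

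**Figure D3:**
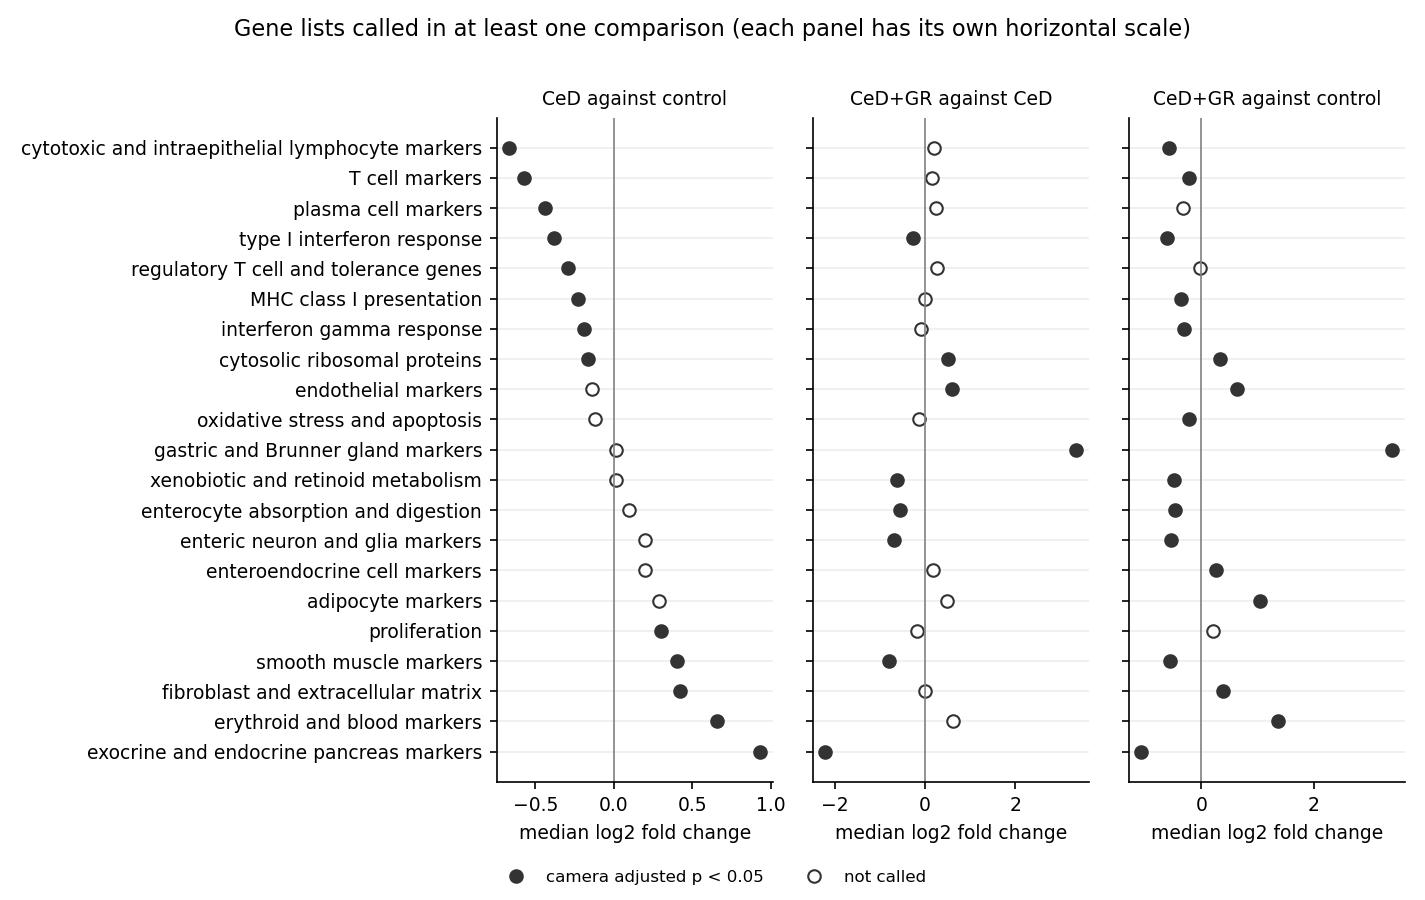
Median log2 fold change (horizontal axis, own scale per panel) of each gene list called in at least 1 comparison, with 1 panel per comparison; filled circles mark a camera adjusted p under 0.05 with the preset correlation of 0.01. Cytotoxic lymphocyte markers lie at -0.67, 0.20 and -0.57 in the 3 panels and gastric markers at 0.01, 3.35 and 3.39, and no list was called with an estimated correlation.

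Among single genes with no overlap between CeD+GR and control, Tfcp2l1, an epithelial transcription factor (ENSMUSG00000026380, chromosome 1, 118627945 to 118685168), averaged 2.92 ± 0.450 FPKM (SD, n = 3) in control and 7.57 ± 1.22 FPKM in CeD+GR. Mmp15 had a log2 fold change of 1.29 (SE 0.24) and Slc15a2 of 1.93 (SE 0.38). Nr0b2, a nuclear receptor that represses bile acid synthesis (ENSMUSG00000037583, chromosome 4, 133553376 to 133556536), averaged 13.3 ± 3.46 and 4.57 ± 2.04 FPKM. Slc16a9 averaged 19.2 ± 1.77 and 3.05 ± 4.81 FPKM, with 8.60 FPKM in CeD+GR 3, and Ppargc1b, a coactivator of mitochondrial genes, had a log2 fold change of -0.94 (SE 0.23). In limma 0 of 14683 genes passed, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 193 higher and 207 lower genes, where freely exchangeable libraries would give 734 in all. Regroupings that keep replicate 1 even over the groups were not counted for this comparison. With limma-voom 0 passed, and 136 higher and 199 lower genes had an unadjusted p under 0.05. The total of 400 also passed 734 on the same genes in some settings. It was 1072 without CeD+GR 1, 959 without CeD+GR 2, 946 with replicates 2 and 3 only and 873 with array weights. With CeD 1 and CeD+GR 3 left out and a term for replicate 1 it was 1193. It was 611 with that term alone and 189 without control 2. In 5.58% of genes the groups did not overlap, against 10% for freely exchangeable libraries, which again need not hold with replicate 1 apart. Without control 1, 1 gene passed, the small nucleolar RNA gene Gm22615, which is lower in CeD+GR (adjusted p = 0.014 in limma, where the smallest adjusted p of any gene was 0.062 to 1 in the other settings). It was singled out after its values were seen and is listed at 0 in control 1 and in all 3 CeD+GR libraries.

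Whether genes that differed in CeD were moved the opposite way by the nanoparticles was asked of the first 2 comparisons, which share the CeD libraries. No gene passed both in limma (0), and limma-voom also called 0 in each. Angptl4 averaged 40.7 ± 6.64, 13.4 ± 4.09 and 36.4 ± 15.3 FPKM (SD, n = 3) in control, CeD and CeD+GR, and Cyp1a1 0.693 ± 0.360, 17.7 ± 20.4 and 0.721 ± 0.764 FPKM. Bok and P2ry10 averaged 12.5 ± 3.52 and 2.85 ± 1.38 FPKM in control, 6.40 ± 1.21 and 1.1 ± 0.681 FPKM in CeD, and 25.8 ± 7.82 and 4.20 ± 1.05 FPKM in CeD+GR. These 4 are among 22 genes with an unadjusted p under 0.05 in both comparisons, all 22 with opposite signs. Shared CeD libraries favour opposite signs with no effect at all. Unchanged groups were simulated by regrouping the residuals of all 9 libraries, with 1 replicate 1 library per group as in the design. They gave 42.8 genes under 0.05 in both comparisons on average, with an SD of 66.9 and a range of 0 to 258. There were 22 or more in 32 of 100 regroupings. So wide a spread cannot judge the 22 genes. Across genes, the log2 fold changes of the 2 comparisons correlated at -0.344. Simulated unchanged groups with 1 group shared gave -0.459 on average (SD 0.415, range -1 to 1, 100 regroupings). The covariance was -0.057 against a simulated -0.179, and 62.3% of genes had opposite signs against a simulated 67.0%. CeD against control and CeD+GR against control, which share the control libraries, correlated at 0.369 against a simulated 0.499, with a covariance of 0.061 against 0.196. These regroupings do not keep replicate 1 even over the groups, as the design does. Regroupings that do gave, for the first 2 comparisons, a correlation of -0.459 (SD 0.526, range -1 to 1), a covariance of -0.128 (SD 0.116) and 67.5% opposite signs. Neither set of regroupings is narrow enough to judge the observed correlation. With 3 libraries per group the shared libraries could not be divided, so part of each overlap may come from sharing them.

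The series was designed to look at transcription factors. Of 1469 genes that the table assigns to a transcription factor family, 807 were tested, and limma passed 0 in each comparison, over all genes or adjusted over the factors alone. The smallest adjusted p over the factors alone was 1 for CeD against control, 0.98 for CeD+GR against CeD and 0.63 for CeD+GR against control. At an unadjusted p under 0.05 there were 0 higher and 1 lower, 7 and 11, and 9 and 14 factors. Nr0b2 was the 1 factor of the first comparison, at 13.3 ± 3.46 FPKM (SD, n = 3) in control and 7.26 ± 0.425 FPKM in CeD, and Tfcp2l1 had the smallest p in the other two, with 3.73 ± 1.03 FPKM in CeD and 7.57 ± 1.22 FPKM in CeD+GR. The fixed list of lymphocyte and inflammatory transcription factors had medians of -0.18 in CeD against control (camera adjusted p = 0.17), -0.01 in CeD+GR against CeD (adjusted p = 0.79) and 0.00 in CeD+GR against control (adjusted p = 0.64). Batf, a factor of activated T and B cells, averaged 0.695 ± 0.307 FPKM in CeD and 2.20 ± 1.43 FPKM in CeD+GR. Tbx21, the T helper 1 factor T-bet, averaged 0.817 ± 0.134, 0.522 ± 0.0816 and 0.181 ± 0.293 FPKM in control, CeD and CeD+GR. Foxp3, the regulatory T cell factor, had 56 reads in all 9 libraries together and was below the level tested.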

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

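The settings added after the data were seen are limma-voom, the term for replicate 1, replicates 2 and 3 only, and the pancreatic library CeD 1 and the gastric library CeD+GR 3 left out, with or without that term; all others were planned. Among 40 medians of gene lists, 837 values under other settings kept the direction of the test and the call, 213 kept that direction and lost the call, and 30 turned the direction of the test. In 4 of the 213 the median turned while the test did not: regulatory T cell genes in CeD against control and enteroendocrine markers in CeD+GR against control among genes of at least 2 FPKM, at 0.067 and -0.014, the latter also without CeD+GR 1, at -0.207, and pancreas markers in CeD against control with limma-voom, at -0.088. Among 67 values of named genes, 1659 kept the sign of the log2 fold change under other settings, whatever its size, and 6 turned direction. Among 7 counts of genes or lists, 166 stayed within 1.5 times of the count given, 9 were larger and 9 were smaller. The counts of genes, with that of opposite changes, are 0 as given and could not become smaller. All 9 smaller values are therefore counts of lists. No gene was called in any comparison under any setting, except for 1 gene in CeD+GR against control without control 1, a range of 0 to 1 over the libraries left out. With array weights 18 lists were called between CeD+GR and CeD, with CeD 1 and CeD+GR 3 left out 16, and with the replicate 1 term as well 17, against 9. Replicates 2 and 3 alone gave 8 lists between CeD and control, against 13, in a fit with fewer libraries. Leaving out 1 library at a time gave 8 to 22 lists in CeD against control, 7 to 19 in CeD+GR against CeD and 10 to 20 in CeD+GR against control. In the latter the 10 came without CeD+GR 3. An estimated correlation and fry each gave 0 lists in every comparison. With the preset correlation, other splits of the 6 libraries of a comparison called 8 to 23 lists, and with an estimated correlation 0. A small adjusted p at the preset correlation therefore does not by itself set the groups apart. Why the tests differ was not tested further.

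Pancreas markers in CeD against control turned to -0.317 with array weights, -1.193 with replicates 2 and 3 only, -1.226 with CeD 1 and CeD+GR 3 left out and -1.204 with the replicate 1 term as well, and ran from -1.226 to 1.899 over the libraries left out. In CeD+GR against CeD they ran from -3.595 to 0.288 and came to 0.431 with replicates 2 and 3 only and 0.000 with both libraries left out. Leaving out CeD 1 alone turned both, and array weights gave CeD 1 a weight of 0.609 against 3.12 and 1.26 for the other CeD libraries; replicates 2 and 3 only leaves out further libraries. For the lists that follow, CeD+GR 3 was among the libraries removed. Gastric markers in CeD+GR against CeD ran from -0.045 to 5.044 and came to -0.056 with both libraries left out and the replicate 1 term. Against control they ran from 0.000 to 5.089 and came to 0.000 with both left out, with or without the term. Enterocyte genes in CeD+GR against CeD ran from -0.896 to 0.293 and came to -0.003 with both left out and the term. Against control they ran from -0.905 to 0.414 and came to 0.414 with both left out and 0.470 with the term. T cell markers in CeD+GR against control ran from -0.620 to 0.112, with 0.112 and 0.113 in these settings. Interferon gamma genes ran from -0.604 to -0.001, with -0.001 and -0.054, and the MHC class I list came to 0.110 with both left out and the term.

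Smooth muscle markers ran from -0.047 to 0.841 over the libraries left out in CeD against control and from -0.822 to 0.016 in CeD+GR against control, where adipocyte markers ran from -0.425 to 1.649. Proliferation genes in CeD against control ran from -0.294 to 0.977, and came to -0.294 with CeD 1 and CeD+GR 3 left out. Among named genes, Tgm2 ran from -0.093 to 0.621 in CeD against control, with -0.006 without control 2 and -0.093 with both libraries left out. Il15 ran from -0.103 to 0.374 and was also below 0 without CeD 2, and Mtor in CeD+GR against CeD ran from -0.801 to 0.003. For these the cause was not tested.

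With the number as a replicate block 0 genes were called in each comparison, and 193, 805 and 643 genes had an unadjusted p under 0.05, against 103, 425 and 400. It called 14, 9 and 17 lists, and the call of pancreas markers in CeD+GR against control ended there at -1.070 (adjusted p = 0.079). The numbers share no stated origin. Of 9 pairs of libraries with the same number, 7 deviated from their group means together with a correlation over 0.1, from -0.12 to 0.71 in all, and 5 of 9 libraries correlated best with a library of their own number. Depth limits the low genes, such as the cytokines with few reads in all libraries together, and the spread between libraries limits the rest. All alternatives listed were run.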

Other observations

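The contrast of replicate 1 with the others and the tests on the gastric genes, on the crypt share and the batch in the replicate 1 libraries, and on the cytotoxic list in replicates 2 and 3 were chosen only after the results were seen; the others were written before. The SE over libraries for the crypt share, the gene length and the dilution was also added after the results were seen. Markers of goblet and tuft cells, secretory and sensory cells of the epithelium, had negative medians in CeD+GR against CeD, in values that did not pass. Goblet cell markers had a median log2 fold change of -0.54 with 9 of 13 members negative (camera adjusted p = 0.095), and tuft cell markers a median of -0.34 with 7 of 11 negative (adjusted p = 0.067). Atoh1, the transcription factor that directs cells to secretory fates, averaged 5.20 ± 0.488 FPKM (SD, n = 3) in control, 4.68 ± 1.49 FPKM in CeD and 2.64 ± 0.861 FPKM in CeD+GR. Muc2, the main intestinal mucin, averaged 113 ± 28.8 and 60.4 ± 24.0 FPKM in CeD and CeD+GR, and Dclk1, a kinase of tuft cells, 1.30 ± 0.350 and 0.532 ± 0.125 FPKM. Every CeD+GR library lay below every CeD library for these 3 genes, none of which passed in limma. The tuft cell gene Alox5ap went the other way, at 0.97 (SE 0.50), as did 4 of 11 tuft members in all. The list means overlapped, at 5.26 to 5.94 in CeD+GR and 5.55 to 5.99 in CeD for goblet cells. For tuft cells they were 1.96 to 2.18 and 1.94 to 2.44 (two-sided exact permutation p = 0.7 for goblet and 0.5 for tuft cells). Without CeD 1 both lists were called lower, at -0.55 for goblet and -0.57 for tuft cells. Over all libraries their adjusted p with an estimated correlation was 0.87 each, and the mean of the goblet list was only -0.11, with 4 of 13 members positive. The tuft median was -0.71 without CeD+GR 1, and the goblet median was -0.36, -0.25, -0.34 and -0.27 without CeD 2, CeD 3, CeD+GR 2 and CeD+GR 3.

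Between the 3 replicate 1 libraries and the 6 others, with the groups in the model, genes of the crypt base stood out. Paneth cell markers had a median log2 difference of 3.99, with 13 of 16 members passing in limma (camera adjusted p = 1.1e-14; adjusted p = 0.51 with an estimated correlation), and the antimicrobial genes Ang4 and Lyz1 were 5.30 and 4.25 higher on the log2 scale (adjusted p = 0.0023 and 0.0093), both chosen after their values were seen. Proliferation genes had a median of 1.46, with 23 of 23 positive (adjusted p = 9.8e-14; adjusted p = 0.63 with an estimated correlation), macrophage and dendritic cell markers 0.86 (adjusted p = 8e-07; adjusted p = 0.63 with an estimated correlation) and smooth muscle markers -1.28, with 14 of 14 negative (adjusted p = 8.9e-10; adjusted p = 0.63 with an estimated correlation). Of 159 tested immunoglobulin variable genes, 159 were higher, with a median of 3.10, and 82 passed. Pancreas markers had a median of 2.52, with 22 of 22 positive (camera adjusted p = 5.4e-05, and 0.92 with an estimated correlation). Their list mean was 6.58 in CeD 1, against 1.78 in control 1 and 0.01 in CeD+GR 1. Endothelial and B cell markers were among others called, at 0.90 and 0.76 (adjusted p = 0.0056 and 0.0085, and 0.87 and 0.63 with an estimated correlation). Cytotoxic lymphocyte markers had a median of -0.14 (adjusted p = 0.72) and enterocyte genes -0.07 (adjusted p = 0.66).

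The replicate 1 libraries stood apart in 446 genes, 304 higher and 142 lower of 14683, where no gene was called between the study's groups. A larger share of crypt tissue alone was taken to raise Paneth, stem cell and proliferation markers alike. The Paneth median exceeded the nearer of the other medians by 2.52 (SE 0.54 over genes). The list means differed by 1.80 (SE 0.47 over libraries). This cannot decide the question, since it assumes that stem cell and proliferation genes are as confined to crypts as Paneth genes. The stem cell and proliferation medians were higher too, at 0.60 and 1.46, and a larger crypt share stays open. Gene length is argued against, since the Paneth median stayed at 4.23 (SE 0.54 over genes) after the median of genes of its length was subtracted, and the list mean at 3.62 (SE 0.33 over libraries). The 446 genes are what a separate animal, library or sequencing batch could give, and since the labels name no batch, this stays open. No biological explanation was tested, since the design gives none for a replicate number.

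Gastric transcripts in CeD+GR 3 may come from stomach or pyloric mucosa in that sample. Of Gkn1, Gkn2, Muc5ac, Tff1 and Gast, genes of the stomach that left out those shared with duodenal Brunner glands, 5 of 5 reached 10 times their highest value elsewhere, at 578.5, 1225, 17.3, 13.6 and 7.05 FPKM. In CeD+GR 1 and 2 the median log2 ratio of the 9 tested list members to control was 0 (SE 0.10 over genes), so these libraries showed no rise. This met the limit set against an effect of the treatment but cannot decide on it. Both libraries held the least Pdx1 and may come from farther along the gut. Their list means of -0.57 and -1 lie near the floor. Gkn3 stood at 18380 FPKM and the pepsinogen gene Pgc at 1007 FPKM in CeD+GR 3, chosen after their values were seen. Tff2 and Muc6 belong to the fixed list of gastric and Brunner gland markers, and Brunner glands of the duodenum were not weighed as their source. Pdx1 was also highest in CeD+GR 3. That source and a change of epithelial identity within the duodenum of this 1 sample were not tested and stay open.

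Among 3 technical explanations weighed for the lower cytotoxic lymphocyte list in CeD, dilution of the mucosa by other tissue stays open. It would lower enterocyte genes too, and their median of 0.10 (SE 0.07 over genes) met the limit written before, which was to lie above -0.22, but that limit was wrong in leaving out the spread between libraries: the list mean differed by 0.11 with an SE of 0.45 over libraries, and fibroblast, smooth muscle and pancreas lists were higher, at 0.42, 0.40 and 0.93. Sampling position stays open as well. With log2 Pdx1 as a covariate the difference of the list mean was -0.88 (SE 0.14), against -0.71 without it. This met the limit written before, but the test cannot decide. Pdx1 hardly varied within control, and most of its spread within groups lay in CeD+GR. There the list mean was 1.95 in CeD+GR 3, with its gastric transcripts, and 2.86 and 3 in CeD+GR 1 and 2. Pdx1 is also a gene of the pancreas, whose transcripts CeD 1 held. The difference between replicate 1 and the others was not decided by a test, since each group holds 1 replicate 1 library and the design balances it; replicates 2 and 3 alone gave a median of -0.65, against -0.67. A change of these lymphocytes in the model was not tested apart from dilution or position and stays open. Counts of the cells in tissue sections, which the data do not hold, would tell it apart from dilution.

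Pdx1 varied widely between libraries, and a candidate explanation is that samples were taken at different distances from the stomach. Pdx1 correlated across the 9 libraries with the mean of 6 other genes of the proximal duodenum (Onecut2, Slc40a1, S100g, Trpv6, Gip and Ghrl), at a Pearson r of 0.834 (two-sided exact permutation p = 0.0048) and a Spearman rho of 0.933 (exact permutation p = 0.00075). This was the 1 relation tested, so the adjusted values are the same. Without CeD+GR 2 and CeD+GR 1, the libraries farthest from the median of Pdx1, r was 0.902. Within replicates 2 and 3, with 6 libraries, it was 0.808 (exact permutation p = 0.062), and replicate 1 has too few libraries for a value. S100g, a calcium-binding protein of duodenal calcium uptake, stood at 3270 FPKM in CeD+GR 3 and at 3.84 FPKM in CeD+GR 2, and the iron exporter gene Slc40a1 at 69.2 and 0.452 FPKM, both chosen after their values were seen. A change of these genes by the challenge or the nanoparticles was not tested apart from position.

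Each comparison allows 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. For genes called, the real split gave 0 in each comparison, so that 10 of 10 splits give as many whatever the data hold and the count decides nothing; the others gave at most 0, 1 and 2. For lists called, 7 of 10 splits gave as many in CeD against control (13 real, at most 23 in the others), 10 of 10 in CeD+GR against CeD (9 and 23) and 6 of 10 in CeD+GR against control (18 and 23). The splits with the most genes at an unadjusted p under 0.05 were CeD 1, CeD 2 and control 1 against the rest, with 1767 against 103 in the real split, CeD+GR 1, CeD+GR 3 and CeD 1, with 2971 against 425, and CeD+GR 1, CeD+GR 3 and control 1, with 3634 against 400. All 3 put the replicate 1 libraries on 1 side, which points to a structure of the samples. With replicates 2 and 3 only, 0 genes were called in each comparison, and 8 lists in CeD against control.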
